A study of Homo sapiens with 8 samples.

How the data were processed

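Gene expression was measured on Affymetrix oligonucleotide arrays in Hep-3B and Huh7 cells, 2 established human hepatoma cell lines. Per the labels' protocols, cells grown in medium with 10% fetal bovine serum were transduced with lentivirus at a multiplicity of infection of 2. The virus carried a short hairpin RNA (shRNA, an RNA that is processed by the cell and directs the destruction of a matching transcript) against KLHL23 or against luciferase, a gene human cells lack, and puromycin selection began after 48 hours. Biotin-labelled RNA from the selected cells was hybridised. The 8 arrays form 4 groups of 2, named by cell line and hairpin (shKLHL23 for knockdown, shLuc for control), and the labels number the arrays of each group 1 and 3. The labels do not say whether these replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. They also give 1 name for the knockdown hairpin in both lines, so effects of KLHL23 loss cannot be separated here from effects of the hairpin on other transcripts.

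The deposited values are log2 expression values, made by the authors with RMA (robust multi-array average) in Affymetrix Expression Console 1.2, per the submitters' processing notes. RMA corrects background, gives every array the same distribution of probe intensities and summarises the probes of each probe set. It shrinks changes of dim probe sets, and it hides any change in the total amount of RNA per cell. The table held 54675 probe sets, and array medians lay between 4.563 and 4.597. Other settings of the authors' processing were not given in the sources used here.

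Probe sets were named from the platform annotation, which paired 41097 with a single gene symbol and 1801 with several; 11777 were unnamed there. Symbols of 41043 probe sets were looked up by gene identifier in a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Each gene was represented by the probe set paired with it alone that had the highest mean over the 8 arrays, with no filter on level, which left 19775 genes.

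Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 values. A linear model (lmFit) with a mean for each of the 4 groups was fitted to all 8 arrays, so that the groups shared an estimate of each gene's spread, and eBayes moderated that estimate. The contrasts were knockdown minus control within each line, the mean of these 2 differences, the Huh7 difference minus the Hep-3B difference, and Huh7 control minus Hep-3B control. The p-values were adjusted by Benjamini-Hochberg over all 19775 genes, and a gene was called changed at an adjusted p under 0.05. Each SE is the moderated standard error of a log2 difference. The number of arrays, 2 per group with 4 residual and 4.59 prior degrees of freedom, limits the precision.

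A set of 27 gene lists was tested with camera, a limma function that asks whether the genes of a list move more than other genes, with its preset correlation of 0.01 between genes and adjustment over the lists of a comparison. The lists covered epithelial and mesenchymal state, the cytoskeleton and matrix, hypoxia, signalling pathways, hepatocyte function, stress responses, proliferation, the Kelch-like family and markers of other liver cell types. The correlation estimated from the data per list, and fry, a limma test of whether a list's genes move on balance in the same direction, were alternatives. Counts of changed members are given after adjustment over all genes and adjusted over the list alone.

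The groups, tests, gene lists, alternative settings and rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls per line among changed genes whose arrays do not overlap between groups. It adds up to 4 changed members per list, or 2 where none changed, the 5 genes in each direction changed alike in both lines with the largest smaller change, and the 3 largest differences between lines in each direction. KLHL23, CDH1, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, ZEB2, TWIST1, HIF1A and NOTCH1 are always given. The camera test of the difference between lines was added after the data had been seen.

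The procedure was tested on simulated data with 200 of the 19775 genes changed. For Hep-3B it recovered 68.7% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 5 unchanged genes among 184 calls. For Huh7 it recovered 65.7% at 1.5-fold, 97% at 2-fold and 100% at 4-fold, with 16 unchanged genes among 191 calls. The simulated noise was independent between genes and had the same spread in all 4 groups. In the real arrays knockdown replicates differed more than control replicates, so these rates can be too high. In Hep-3B ATF3, at -2.09 with knockdown arrays of 8.09 and 5.84, was not called. The alternative settings were a further quantile normalization, median centring, a filter on dim genes, the mean of a gene's probe sets, removal of probe sets prone to cross-hybridization, another variance model, fits per line, array weights, replicate numbers as a block, each array left out, tests of all probe sets and a fold threshold of 1.5.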

Results

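The study asked how the transcriptome of hepatoma cells responds to loss of KLHL23, a member of the Kelch-like family, many of whose proteins bring substrates to cullin 3 ubiquitin ligases. Its title places KLHL23 in epithelial-mesenchymal transition (EMT), the change of epithelial cells to a motile, fibroblast-like state. Transcript levels were measured on 8 arrays, with 2 control and 2 knockdown arrays in each of Hep-3B and Huh7, lines grown from human liver cancers. Replicates correlated at 0.998 in both control groups, at 0.996 in Hep-3B knockdown and at 0.995 in Huh7 knockdown. The SD of the difference between replicates over genes was 0.157 and 0.171 in the control groups of Hep-3B and Huh7, and 0.222 and 0.25 in their knockdown groups, so knockdown replicates differed more.

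KLHL23 transcript was lower in all 4 knockdown arrays than in any control array. In Huh7 it fell by 2.05 on the log2 scale (SE 0.27, n = 2 per group, limma adjusted p = 0.00363), to 23.4% and 25% of the control mean in replicates 1 and 3. In Hep-3B the difference was -1.14 (SE 0.27, n = 2 per group, limma adjusted p = 0.0833), which did not pass the threshold. The arrays were uneven, at 65.5% of control in replicate 1 and 31.4% in replicate 3. A brighter probe set that KLHL23 shares with the readthrough locus PHOSPHO2-KLHL23 gave -2.40 in Huh7 and -1.17 in Hep-3B. Of 2 dim probe sets of these loci, 1 with array values of 2.89 to 3.85 gave 0.32 in Huh7 and -0.23 in Hep-3B and the other, at 1.69 to 2.15, gave 0.07 and 0.12. Neither passed over all probe sets (limma adjusted p = 0.233 and 0.515 for the first, 0.824 and 0.775 for the second). The difference between the lines, -0.91 (SE 0.38), did not pass the threshold (limma adjusted p = 0.316). The control levels of the lines differed by 0.06 (limma adjusted p = 0.911). Without Hep-3B knockdown replicate 1 the Hep-3B difference was -1.67 and without replicate 3 it was -0.61. Either fit leaves a lone array in that group, and the spread between its 2 unlike arrays is lost. With array weights the difference of -1.14 passed (limma adjusted p = 0.0424; range over alternatives 0.000784 to 0.36).

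**Figure D1:**
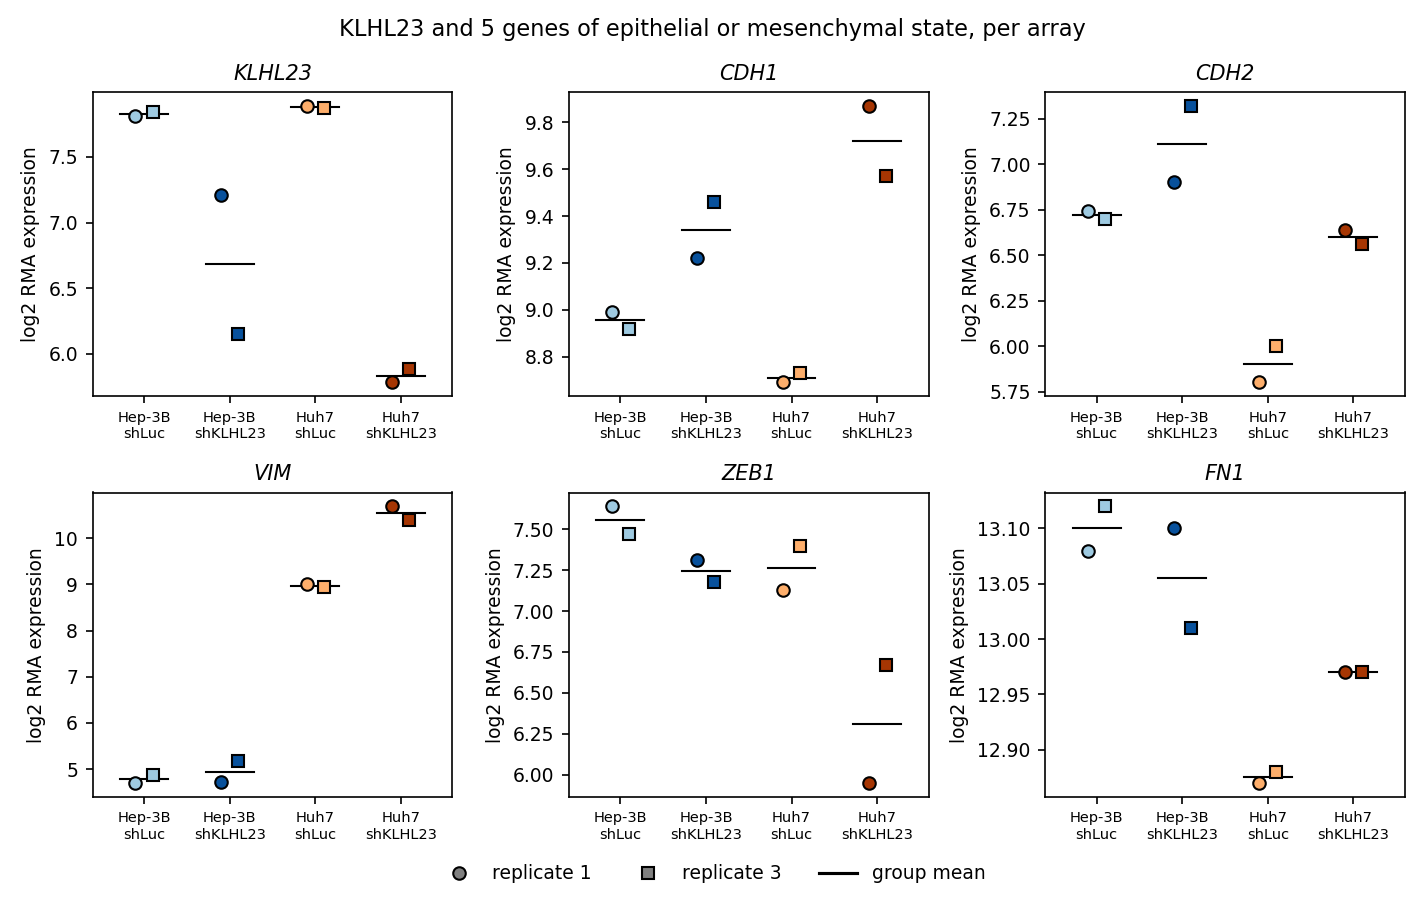
Log2 RMA expression of KLHL23, CDH1, CDH2, VIM, ZEB1 and FN1 in each of the 8 arrays, by group; circles are replicate 1, squares replicate 3, black lines group means, and each vertical axis has its own range. KLHL23 was uneven between the Hep-3B knockdown arrays, at 7.21 and 6.15, and close between the Huh7 knockdown arrays, at 5.78 and 5.88.

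The first comparison was KLHL23 knockdown in Hep-3B. MT1M, a metal-binding metallothionein, rose most, by 3.54 (SE 0.32, limma adjusted p = 0.00743), and MT1F rose by 1.95. The control arrays of MT1M lay at 2.66 and 2.58, below the lower quartile of those arrays (3.08 and 3.10), and the deposited values carry no background call, so the size and rank of its rise are uncertain. CYP17A1, an enzyme of steroid hormone synthesis, rose by 2.66 (SE 0.28, limma adjusted p = 0.0136), and STAR, which carries cholesterol into mitochondria for that synthesis, by 1.78. Of the 2 probe sets of CYP17A1 1 rose. The transcription factor MAF rose by 2.08, the acyl-CoA synthetase ACSM2A by 1.99, ERICH4 by 1.98, the alcohol dehydrogenase ADH4 by 1.93, the interferon-induced IFI27 by 1.90 and the sterol synthesis enzyme MSMO1 by 1.71. The largest falls were those of the sulfotransferase SULT1C4 (-1.38, SE 0.18, limma adjusted p = 0.021), the G protein subunit GNG4 (-1.25), ZNF711 (-1.19), the vesicular amine transporter SLC18A2 (-1.16), the complement receptor C5AR1 (-1.16), ACTA1 (-1.04), TMEM145 (-0.99), LONRF3 (-0.95), RAP2B (-0.92) and PARAIL (-0.91). The knockdown arrays of C5AR1, at 3.10 and 2.73, lay below their lower quartiles (3.12 and 3.08). The size and rank of its fall are therefore uncertain as well. In all, 137 of 19775 genes changed, 106 higher and 31 lower, and 68 of them by at least 2-fold. That count and its share of rises rest on few arrays: it was 1134 without knockdown replicate 1 (603 higher), 16 without knockdown replicate 3, 0 without either Hep-3B control array, 25 without either Huh7 control array and 54 without either Huh7 knockdown array. It was also 0 when Hep-3B was fitted alone, 850 with an intensity trend and robust eBayes together (479 higher), 671 with array weights (352 higher) and 623 over all probe sets (269 higher). Leaving out an array that differs from its replicate lowers the estimated spread whatever the reason, so calls made that way are weak evidence. At an unadjusted limma p under 0.05 there were 3491 genes in Hep-3B and 5441 in Huh7.

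Of the 27 gene lists, 9 moved in Hep-3B with the preset correlation and 0 with an estimated correlation or with fry. The cholesterol and fatty acid synthesis list moved up most clearly (mean 0.64, camera adjusted p = 1.43e-17), although this gave adjusted p = 0.346 with an estimated correlation. Of its 34 measured genes 6 rose and 0 fell, and 26 rose adjusted over the list alone. HMGCS1 (1.70), IDI1 (1.65) and SQLE (1.26), enzymes of the mevalonate and sterol pathway, rose with MSMO1. The hepatocyte metabolic enzymes moved up (mean 0.27, camera adjusted p = 0.000126; adjusted p = 0.346 with an estimated correlation). Of 66 genes 7 rose and 0 fell, with 21 changed adjusted over the list alone. They included CYP7A1, the rate-limiting enzyme of bile acid synthesis (1.54, from control values of 2.63 and 2.55, also below the lower quartile), CYP4F2 (1.33) and the fatty acid carrier FABP1 (1.06). Hepatocyte secreted proteins moved up (mean 0.14, camera adjusted p = 0.0111; adjusted p = 0.76 with an estimated correlation), with 2 of 63 risen, the thyroxine carrier TTR (1.58) and APOM (1.24), and 18 changed adjusted over the list alone. That list did not pass without knockdown replicate 3 (camera adjusted p = 0.0601). Of 11 measured histone genes H2BC4 (1.08) and H2BC9 (1.04) rose, with 6 risen adjusted over the list alone (camera adjusted p = 8.73e-06; adjusted p = 0.346 with an estimated correlation).

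The other 5 lists moved down in Hep-3B. Targets of hypoxia-inducible factor, the regulator of the response to low oxygen, had a mean of -0.56 (camera adjusted p = 1.2e-16; adjusted p = 0.346 with an estimated correlation). None of these 48 genes passed over all genes (0 called), and 31 passed adjusted over the list alone, 30 of them lower. DDIT4 (-1.71, limma adjusted p = 0.276) and ANKRD37 (-1.68, limma adjusted p = 0.0728) had the largest differences. Both rest on knockdown replicate 3: without it they were at -0.75 and -0.97, and without replicate 1 at -2.66 and -2.39. Of the 2 probe sets of ANKRD37 1 fell. The immediate early and AP-1 list had a mean of -0.52 (camera adjusted p = 2e-14; adjusted p = 0.346 with an estimated correlation), with 0 of 38 called, 19 lower adjusted over the list alone, and ATF3 at -2.09 (limma adjusted p = 0.107) and EGR1 at -1.59 (limma adjusted p = 0.135). Without knockdown replicate 3 ATF3 was at -0.97 and EGR1, for which another probe set then stood, at -0.88. Without replicate 1 they were at -3.22 and -2.55, values that rest on a lone knockdown array. Among all probe sets tested, a dimmer one of each passed, at -1.61 for ATF3 (limma adjusted p = 0.0369) and -1.14 for EGR1 (limma adjusted p = 0.0361). The unfolded protein and amino acid response had a mean of -0.40 (camera adjusted p = 0.000167; adjusted p = 0.483 with an estimated correlation). Its only called member of 44, the endoplasmic reticulum chaperone partner DNAJB9, rose by 0.97, against the direction of the list, of which 29 genes passed adjusted over the list alone. NF-kB and inflammatory targets had a mean of -0.27 (camera adjusted p = 8.24e-05; adjusted p = 0.421 with an estimated correlation), and 2 of 37 fell, ICAM1 (-0.75) and LIF (-0.56), with 11 adjusted over the list alone. Liver transcription factors had a mean of -0.18 (camera adjusted p = 0.00192; adjusted p = 0.346 with an estimated correlation), and 1 of 25 fell, CEBPD (-0.65), with 12 changed adjusted over the list alone. The difference between 3' and 5' probe sets of ACTB, a measure of RNA integrity, was 0.442 and 0.537 in the Hep-3B control arrays and 0.737 and 0.753 in the knockdown arrays. That of GAPDH was 0.117 and 0.12 in control and 0.223 and 0.236 in knockdown arrays, so both moved with these groups.

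The other 18 lists did not pass in Hep-3B. Single members changed in several of them. DKK4 (1.42) rose among 26 Wnt target and feedback genes, where 7 passed adjusted over the list alone. MMP7 (1.17) rose among 38 matrix remodelling genes (1 adjusted over the list alone), CFL2 (0.94) among 65 actin and focal adhesion genes (3), FBN1 (0.76) among 47 mesenchymal genes (4), KLHL42 (0.63) among 49 Kelch-like and cullin 3 genes (2) and LYVE1 (1.30) among 16 endothelial markers (1). IFI27 and CMPK2 (1.49) rose among 52 interferon-stimulated genes, with 3 adjusted over the list alone, and ICAM1 fell among 35 hepatic progenitor genes, with 6. No member was called in the epithelial (46 measured), EMT transcription factor (23), Notch (37), TGF-beta (37), cell cycle (63), p53 (31), KEAP1-NRF2 (31), stellate cell and fibroblast (16), blood and macrophage (16) or cholangiocyte (17) lists, where 3, 1, 3, 5, 0, 12, 2, 0, 0 and 2 members passed adjusted over the list alone. The members furthest from 0 that did not pass included INHBE (-1.56, limma adjusted p = 0.134), SLC7A11 (-1.54, limma adjusted p = 0.177), PMAIP1 (-1.18, limma adjusted p = 0.112), HES1 (-0.95, limma adjusted p = 0.0553), GDF15 (-0.90, limma adjusted p = 0.0926), JUNB (-0.89, limma adjusted p = 0.0815) and ELF3 (-0.85, limma adjusted p = 0.0633). These rest in part on knockdown replicate 3 as well: without it the 7 were at -0.76, -0.75, -0.76, -0.67, -0.49, -0.56 and -0.58. Without replicate 1, with a lone knockdown array left, they were at -2.36, -2.32, -1.61, -1.23, -1.30, -1.22 and -1.11. Among all probe sets tested, 2 of HES1 passed (-0.95 each, limma adjusted p = 0.043 and 0.0361), as did 1 dimmer probe set of SLC7A11 (-1.90, limma adjusted p = 0.0178). The interferon list passed upwards without knockdown replicate 1 (camera adjusted p = 0.0449). The mesenchymal and hepatic progenitor lists had a positive median beside a negative mean and test, and the Wnt and stellate cell lists a negative median and test beside a positive mean.

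**Figure D2:**
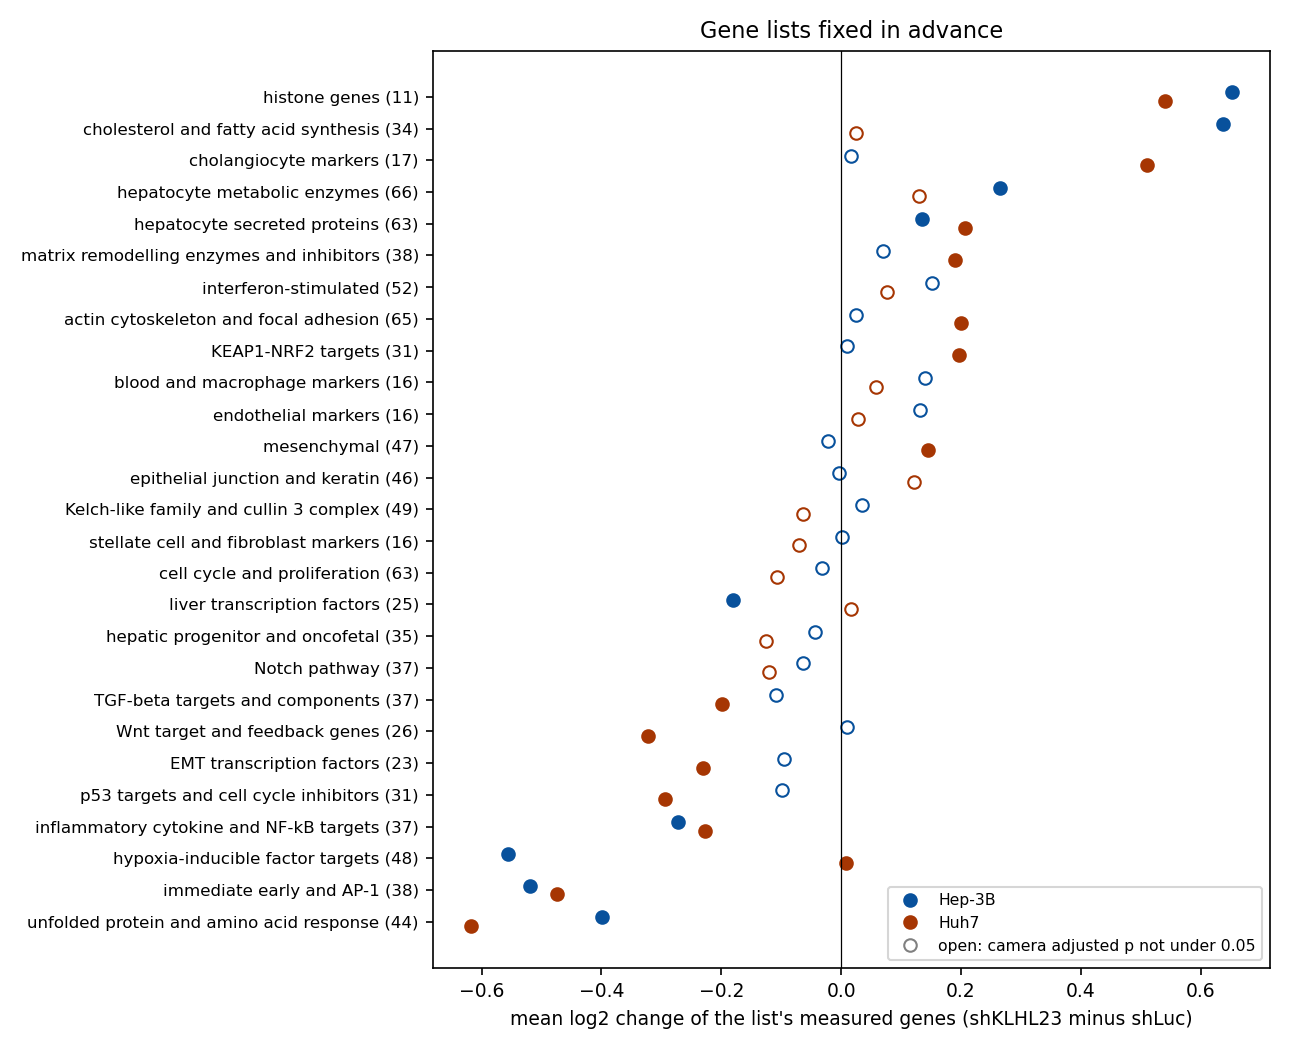
Mean log2 change (knockdown minus control) of the measured members of each of the 27 gene lists in Hep-3B (blue) and Huh7 (brown), with the number measured in parentheses; filled points had a camera adjusted p under 0.05 with the preset correlation. The unfolded protein and immediate early lists lie below 0 in both lines, and the cholesterol list lies at 0.64 in Hep-3B and 0.02 in Huh7.

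The second comparison was KLHL23 knockdown in Huh7. MMP7, a matrix metalloproteinase of epithelial cells, rose most, by 3.52 (SE 0.16, limma adjusted p = 7.26e-05). It was followed by CPT1A, which admits fatty acids to mitochondria for oxidation (2.88, SE 0.11, limma adjusted p = 2.4e-05), and the complement component C6 (2.84, SE 0.14, limma adjusted p = 9.3e-05). The death ligand TNFSF10 (2.41), the phospholipase PLA1A (2.25), the defensin DEFB1 (2.21), the alcohol dehydrogenase ADH1B (2.16), osteopontin SPP1 (2.10), the nuclear receptor NR0B2 (1.97) and MT1G (1.95) also rose. The largest falls were those of the activin subunit INHBE (-2.89, SE 0.47, limma adjusted p = 0.00705), the lipase inhibitor G0S2 (-2.83), the stress-induced mTOR inhibitor DDIT4 (-2.82), the pseudogene VNN3P (-2.40), the stress-induced transcription factor ATF3 (-2.25), ZFAND1 (-2.06), KLHDC7B (-2.06), KLHL23 itself, the fetal hepatocyte marker DLK1 (-1.98) and ANGPTL8 (-1.97). Of the 2 probe sets of DLK1 1 fell. In all, 2666 genes changed, 1137 higher and 1529 lower, and 266 of them by at least 2-fold. Without knockdown replicate 1 DDIT4, whose knockdown arrays lay at 7.03 and 9.38, was at -1.64 (limma adjusted p = 0.171). KLHDC7B was at -0.68 and -0.45 without control replicate 1 or 3, when another probe set stood for it, and did not pass (limma adjusted p = 0.124 and 0.279). The count was 562 without control replicate 3, 566 without control replicate 1, 1447 without knockdown replicate 1 and 1578 when Huh7 was fitted alone.

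In Huh7, 15 lists moved with the preset correlation, 0 with an estimated correlation and 13 with fry. Of 44 genes of the unfolded protein and amino acid response 20 fell and 0 rose, with 26 changed adjusted over the list alone (mean -0.62, camera adjusted p = 0.000112; adjusted p = 0.421 with an estimated correlation). INHBE and ATF3 fell with CHAC1, which degrades glutathione (-1.70), and the pseudokinase TRIB3 (-1.51). The immediate early and AP-1 list had 11 of 38 fallen and 1 risen, with 17 adjusted over the list alone (mean -0.48, camera adjusted p = 1.45e-05; adjusted p = 0.425 with an estimated correlation), including the transcription factors KLF4 (-1.81) and KLF10 (-1.70) and the growth factor EREG (-1.66). Of the 2 probe sets of EREG 1 fell. Of 31 p53 targets and cell cycle inhibitors 12 fell and 2 rose, with 17 adjusted over the list alone (camera adjusted p = 0.00421; adjusted p = 0.197 with an estimated correlation). PMAIP1 (-1.91), SESN2 (-1.40), TNFRSF10B (-1.29) and GADD45A (-1.23), which are also induced by integrated stress signalling, fell, while the cell cycle inhibitor CDKN1A rose by 1.04. NF-kB and inflammatory targets had 9 of 37 fallen and 3 risen, with 16 adjusted over the list alone (camera adjusted p = 0.0218; adjusted p = 0.505 with an estimated correlation), with CXCL3 (-1.66) and TNFAIP3 (-0.92) lower and CX3CL1 (1.01) and IL32 (0.93) higher. Without knockdown replicate 1 CHAC1 was at -1.06, CX3CL1 at 0.65 and IL32 at 0.60, and IL32 did not pass (limma adjusted p = 0.0623). The ACTB 3' minus 5' difference was 0.873 and 0.833 in the Huh7 control arrays and 0.525 and 0.546 in the knockdown arrays, opposite in direction to Hep-3B. That of GAPDH did not separate the Huh7 groups, at 0.132 and 0.0887 in control and 0.148 and 0.112 in knockdown arrays.

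Signalling lists also moved down in Huh7. Of 26 Wnt target and feedback genes 13 fell and 0 rose, and 15 changed adjusted over the list alone (mean -0.32, camera adjusted p = 4.38e-05; adjusted p = 0.187 with an estimated correlation). They included NKD1 (-1.02), MYC (-0.83), the secreted inhibitor WIF1 (-0.82) and the receptor FZD7 (-0.78). Of 37 TGF-beta targets and components 9 fell and 2 rose, with 12 adjusted over the list alone (camera adjusted p = 0.046; adjusted p = 0.441 with an estimated correlation), and they included INHBE, SKIL (-0.78) and the coreceptor TGFBR3 (-0.66). Of 37 Notch genes 5 fell, with 6 adjusted over the list alone, among them the protease ADAM17 (-0.99), the target HEY1 (-0.84) and the ligand JAG1 (-0.54), and the list did not pass camera (adjusted p = 0.127).

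The actin cytoskeleton and focal adhesion list moved up in Huh7, with 25 of 65 risen and 3 fallen and 34 changed adjusted over the list alone (mean 0.20, camera adjusted p = 1.45e-05; adjusted p = 0.326 with an estimated correlation). The actin-binding TMSB4X (1.09), the myosin light chain MYL9 (0.95) and the actin crosslinker ACTN4 (0.89) rose, and FERMT2, an activator of integrins, fell (-1.15, SE 0.09, limma adjusted p = 0.000503). Of 38 matrix remodelling genes 7 rose and 3 fell, with 12 adjusted over the list alone (camera adjusted p = 0.0332; adjusted p = 0.421 with an estimated correlation), with TIMP2 (1.2) higher beside MMP7 and the collagen crosslinking enzyme LOX (-1.15) lower. Cholangiocyte markers, genes of bile duct cells, had 6 of 17 risen and 1 fallen, with 9 adjusted over the list alone (mean 0.51, camera adjusted p = 0.00154; adjusted p = 0.197 with an estimated correlation). Those were led by DEFB1, SPP1, the keratin KRT19 (1.32) and ANXA4 (1.05), all of which liver cancer cells can express as well. Targets of KEAP1-NRF2, the regulator of antioxidant defence, had 12 of 31 risen and 3 fallen, with 19 adjusted over the list alone (camera adjusted p = 0.000378; adjusted p = 0.205 with an estimated correlation), and AKR1B10 (1.24), UGDH (0.93), GPX2 (0.75) and HMOX1 (0.73) rose. Hepatocyte secreted proteins had 13 of 63 risen and 4 fallen, with 19 adjusted over the list alone (camera adjusted p = 0.00171; adjusted p = 0.56 with an estimated correlation), with SERPINA7 (1.45), C4BPB (1.35) and TTR (1.23) higher and the iron regulator HAMP (-1.14) lower. Without knockdown replicate 1 LOX was at -0.67 and did not pass (limma adjusted p = 0.185). Among 11 histone genes H2BC12 rose by 1.18 (0.71 without knockdown replicate 1), with 7 adjusted over the list alone (camera adjusted p = 0.00124; adjusted p = 0.421 with an estimated correlation).

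The hypoxia list passed camera upwards in Huh7 (adjusted p = 0.046; adjusted p = 0.654 with an estimated correlation), although its mean was 0.01 and its median 0.10. Of its 48 genes 9 rose and 3 fell, with 18 adjusted over the list alone. NDRG1 (1.75) and BHLHE41 (1.2) rose, and DDIT4, STC2 (-1.51) and LOX fell. The last 3, without knockdown replicate 1, were at -1.64, -0.83 and -0.67 and did not pass. The remaining lists did not pass. Hepatocyte metabolic enzymes had 9 of 66 risen and 5 fallen, 14 adjusted over the list alone, with CYP3A5 (1.58) higher and the urea cycle enzyme CPS1 (-1.54) lower. The Kelch-like and cullin 3 list had 7 of 49 risen and 11 fallen, with 21 adjusted over the list alone. KLHL5 (-1.54), KBTBD6 (-1.33), KLHL2 (-1.04) and KLHL28 (-0.96) fell with KLHL23, which is the targeted gene. Hepatic progenitor genes had 5 of 35 risen and 9 fallen (16 adjusted over the list alone), with PROM1 (1.13, and 0.73 without knockdown replicate 3) higher, and interferon-stimulated genes 6 of 52 risen and 4 fallen (14), with IFITM2 (0.81), EIF2AK2 (0.81) and IFITM3 (0.75) higher and CXCL10 (-1.12) lower. EIF2AK2 was at 0.19 without knockdown replicate 3, when another probe set stood for it (limma adjusted p = 0.281). Liver transcription factors had 2 of 25 risen, NR0B2 and CREB3L3 (1.35), and 3 fallen, among them CEBPB (-1.08) and FOXA1 (-0.51), with 6 adjusted over the list alone. Of 34 cholesterol and fatty acid synthesis genes 4 fell, GPAM (-0.64), ELOVL6 (-0.47), SREBF1 (-0.37) and ELOVL5 (-0.35), and 0 passed adjusted over the list alone. Without knockdown replicate 1 GPAM was at -0.35 and ELOVL6 at -0.27, and neither passed (limma adjusted p = 0.0722 and 0.124). Of 63 cell cycle genes KIF20A (0.50) and PCNA (0.37) rose and PRC1 (-0.66, and -0.38 without knockdown replicate 1, limma adjusted p = 0.107) and CDT1 (-0.44) fell, with 0 adjusted over the list alone. FBLN1 fell (-0.71) among 16 stellate cell and fibroblast markers, with 1 adjusted over the list alone, and 0 of 16 endothelial and 0 of 16 blood and macrophage markers changed. The probe set that stands for the endothelial marker PECAM1 was at 0.44 and did not pass (limma adjusted p = 0.069). It passed as higher among genes above the median level (limma adjusted p = 0.0452). A dim probe set of PECAM1 passed in the other direction among all probe sets (-0.99, limma adjusted p = 0.00438). The hepatic progenitor list had a positive median beside a negative mean and test, the liver transcription factors a positive mean beside a negative median and test, and the endothelial markers a negative median beside a positive mean and test.

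Several list results in Huh7 rested on single arrays or on the test used; the camera values here use the preset correlation. Without knockdown replicate 1 the cell cycle list turned from a mean of -0.107 to 0.107 and passed upwards (camera adjusted p = 0.00349), and without knockdown replicate 3 it passed downwards (-0.321, camera adjusted p = 4.87e-10). The estimated correlation of its genes was 0.77, far above the preset 0.01, and with it the list of all arrays had camera adjusted p = 0.852, so neither turn is firm. Without replicate 1 the matrix remodelling list did not pass (camera adjusted p = 0.162) and hepatocyte metabolic enzymes passed upwards (camera adjusted p = 0.0136). Without replicate 3 the hypoxia (camera adjusted p = 0.239), TGF-beta (0.27), hepatocyte secreted (0.615), NF-kB (0.292) and p53 (0.0511) lists did not pass. The NF-kB list did not pass without control replicate 1 (camera adjusted p = 0.0583). Without control replicate 3 the TGF-beta list did not pass (camera adjusted p = 0.223) and hepatocyte metabolic enzymes passed upwards (0.0366). The hypoxia list also did not pass without any of the 4 Hep-3B arrays or Huh7 control replicate 1 (camera adjusted p of 0.055 to 0.0949). With fry the Notch (adjusted p = 0.0125), hepatic progenitor (0.0371), Kelch-like (0.0458) and hepatocyte metabolic (0.0474) lists passed as well. The hypoxia (adjusted p = 0.266), TGF-beta (0.0689), hepatocyte secreted (0.118), NF-kB (0.1), immediate early (0.0663) and histone (0.078) lists did not.

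Genes of epithelial and mesenchymal state bear on the question in the study's title. In Huh7, CDH1, the epithelial cadherin, rose by 1.01 (SE 0.13, limma adjusted p = 0.00284), and mesenchymal genes rose with it: CDH2 by 0.71 (limma adjusted p = 0.015), VIM by 1.58 (limma adjusted p = 0.00165), TAGLN by 1.81 (limma adjusted p = 0.00368) and MYL9. ZEB1, a repressor of CDH1, fell by 0.96 (SE 0.21, limma adjusted p = 0.0196). It was at -0.60 without knockdown replicate 1, which did not pass (limma adjusted p = 0.0552). Without that array LOX was at -0.67 (limma adjusted p = 0.185). Of 46 epithelial junction and keratin genes 9 rose, with KRT19, the protease inhibitor SPINT1 (1.31) and CLDN4 (0.88), and 4 fell. Adjusted over the list alone 16 changed. The list did not pass camera (adjusted p = 0.125) but passed fry upwards (adjusted p = 0.0371). For KRT19, CLDN4 and MYL9 1 of 2 probe sets rose, and 0 passed as lower. The 47 mesenchymal genes passed camera upwards (6 risen, LOX fallen, 8 adjusted over the list alone, camera adjusted p = 0.0295; adjusted p = 0.505 with an estimated correlation). They did not pass with fry (adjusted p = 0.0691) or without knockdown replicate 1 (camera adjusted p = 0.123). The 23 EMT transcription factors moved down (5 fallen, 6 adjusted over the list alone, camera adjusted p = 0.00529; adjusted p = 0.354 with an estimated correlation), with ID1 (-0.60), SOX9 (-0.56) and SOX4 (-0.49) lower beside ZEB1. In Hep-3B none of the fixed set passed: CDH1 was at 0.39 (limma adjusted p = 0.156), CDH2 at 0.39 (limma adjusted p = 0.199), VIM at 0.15 (limma adjusted p = 0.703) and ZEB1 at -0.31 (limma adjusted p = 0.495). CDH2 there was at 0.61 without Hep-3B knockdown replicate 1 and at 0.18 without replicate 3. FN1 (-0.04 in Hep-3B and 0.09 in Huh7), SNAI1 (-0.07 and 0.08), SNAI2 (0.09 and -0.28), ZEB2 (-0.23 and -0.02), TWIST1 (0.05 and -0.02), HIF1A (-0.05 and -0.26) and NOTCH1 (-0.16 and -0.35) did not pass in either line. Control means were 2.70 in Hep-3B and 2.58 in Huh7 for SNAI2, 2.98 and 2.79 for ZEB2, and 2.18 and 2.18 for TWIST1. These lay below the lower quartiles of the control arrays (3.08 to 3.12), so a fall of these genes could hardly be seen. NOTCH1 in Huh7 was at -0.58 without Huh7 knockdown replicate 3 and at -0.12 without replicate 1. The FN1 value comes from the brightest of 7 probe sets of that gene, at a mean level of 13 near the top of the arrays' range. In Hep-3B 2 others, examined after the values were seen, fell, at mean levels of 8.83 (-1.27, limma adjusted p = 0.0224 over all probe sets) and 4.36 (-0.94, limma adjusted p = 0.0256). In Huh7 0 of the 7 passed. The difference between lines passed for VIM (1.43, SE 0.23, limma adjusted p = 0.0356) and TAGLN, and not for CDH1 (0.62, limma adjusted p = 0.148) or ZEB1 (-0.64, limma adjusted p = 0.358). VIM had a control mean of 4.79 in Hep-3B, near the array medians, and 8.97 in Huh7. Since RMA shrinks changes of dim probe sets, its change in Hep-3B may be understated.

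Changes common to both lines were led upwards by MT1M (3.54 in Hep-3B and 1.84 in Huh7), MAF (2.08 and 1.79), MT1G (1.69 and 1.95), MT1X (1.67 and 1.68) and MT1H (1.66 and 1.71). Of the 6 probe sets of MAF 3 rose in Hep-3B and 5 in Huh7. Among all probe sets tested 1 and 3 of them passed, and 0 passed as lower. The values of MT1G, MT1X and MT1H come from probe sets prone to cross-hybridization between family members. The other probe set of MT1G, dim at 3.09, was at 0.20 and 0.21 and did not pass. Downwards they were led by PARAIL (-0.91 and -1.49), LONRF3 (-0.95 and -0.71), the centriole protein gene SPICE1 (-0.65 and -0.84), SEPTIN7-DT (-0.76 and -0.57) and the cilium gene LCA5 (-0.64 and -0.56). Of the 2 probe sets of SPICE1 2 fell in Hep-3B and 1 in Huh7. LCA5 was at -0.42 in Hep-3B without Hep-3B knockdown replicate 3, which did not pass (limma adjusted p = 0.588). It was at -0.94 in Huh7 without that array or Hep-3B control replicate 1. In each of these settings another probe set stood for it. Of the genes changed in each line 36 were higher in both, against 6.09 for independent lists, and 12 were lower in both, against 2.40. Another 8 changed in opposite directions. The 2 differences share no array, but their tests share an estimate of each gene's spread from all 8 arrays. The calls are therefore not independent, and part of the excess may come from that. Over all genes, which are not independent replicates, the log2 changes of the lines correlated with r = 0.429 (Spearman's rho 0.357), and 60.6% had the same sign. On average over the lines 3089 genes changed, 1503 higher and 1586 lower. Of the lists, 16 moved on average with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.311. The immediate early list had 20 of 38 fallen on average and the unfolded protein and amino acid response 25 of 44 fallen and 6 risen, with camera adjusted p = 2.64e-11 and 5.62e-05 (adjusted p = 0.311 and 0.323 with an estimated correlation). The average count was 1165 without Hep-3B control replicate 3, 1445 without Hep-3B control replicate 1, 1527 without Hep-3B knockdown replicate 3, 1320 without Huh7 control replicate 1 and 1403 without Huh7 control replicate 3.

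**Figure D3:**
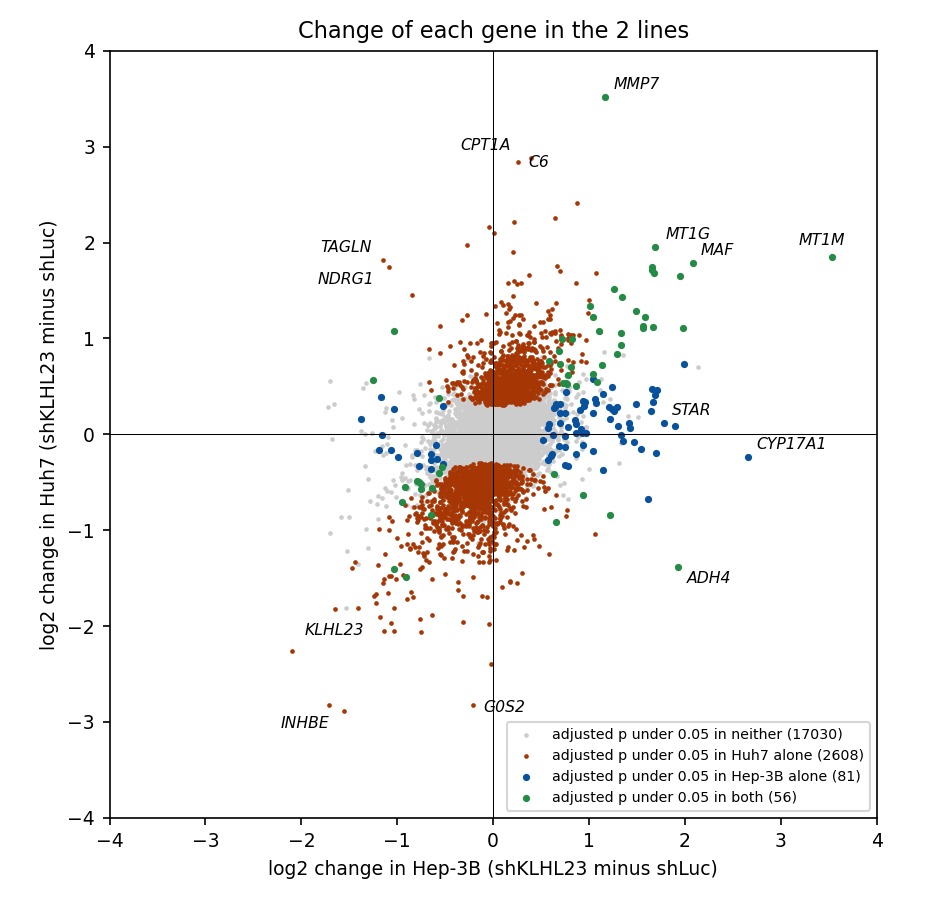
Log2 change of each of 19775 genes in Hep-3B (horizontal axis) and Huh7 (vertical axis), knockdown minus control, coloured by the line in which the limma adjusted p was under 0.05. The metallothioneins and MAF lie at the upper right, and ADH4 lies at 1.93 in Hep-3B and -1.38 in Huh7.

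The response differed between the lines, as tested by the difference of the 2 changes, for 249 genes, 88 with a higher and 161 with a lower value in Huh7. The change was larger in size in Huh7 for 201 of them and in Hep-3B for 48, and 165 had opposite signs. KLHL23 stood at 65.5% and 31.4% of control in the Hep-3B knockdown arrays and at 23.4% and 25% in those of Huh7. The test alone therefore does not separate a response of the line from a difference in knockdown strength. Of the 249 genes 8 changed in both lines, in opposite directions. Weaker silencing would shrink a change rather than reverse it, so these 8 argue against knockdown strength alone. TAGLN, an actin-binding protein of smooth muscle, differed by 2.96 (SE 0.34, limma adjusted p = 0.0098), rising in Huh7 and standing at -1.15 in Hep-3B (limma adjusted p = 0.0699). NDRG1, a stress and hypoxia gene, differed by 2.84 in the same way, with -1.09 in Hep-3B (limma adjusted p = 0.0746), and C6 differed by 2.57, with 0.26 in Hep-3B (limma adjusted p = 0.38). In Hep-3B TAGLN and NDRG1 were at -0.74 and -0.65 without knockdown replicate 3, and at -1.56 and -1.53 without replicate 1. ADH4 rose in Hep-3B and fell in Huh7 (-1.38, limma adjusted p = 0.00736), a difference of -3.31 (SE 0.32, limma adjusted p = 0.00837). CYP17A1 differed by -2.90, with -0.24 in Huh7 (limma adjusted p = 0.647), and G0S2 by -2.62, with -0.21 in Hep-3B (limma adjusted p = 0.769). The Hep-3B controls of G0S2 lay at 4.80 and 4.99, near the array medians, against 9.48 in both Huh7 controls. A fall as large as that in Huh7 could hardly be seen in Hep-3B. Of the lists, 10 differed between lines with the preset correlation. The hypoxia list was higher in Huh7 (mean difference 0.56, camera adjusted p = 1.87e-16; adjusted p = 0.208 with an estimated correlation). The cholesterol list was lower (-0.61, camera adjusted p = 5.11e-12; adjusted p = 0.377 with an estimated correlation). The Wnt list was lower (-0.33, camera adjusted p = 0.000104; adjusted p = 0.144 with an estimated correlation). The actin list was higher in Huh7 (0.175, camera adjusted p = 3.33e-06; adjusted p = 0.208 with an estimated correlation). So were the KEAP1-NRF2 (0.19) and cholangiocyte (0.49) lists, both with camera adjusted p = 0.000141 (adjusted p = 0.208 and 0.144 with an estimated correlation). The epithelial list (0.12, camera adjusted p = 0.0209; adjusted p = 0.208 with an estimated correlation) and the mesenchymal list (0.17, camera adjusted p = 0.0247; adjusted p = 0.595 with an estimated correlation) were both higher in Huh7. The liver transcription factors were higher (0.20, camera adjusted p = 0.0351; adjusted p = 0.218 with an estimated correlation) and the p53 list lower (-0.195, camera adjusted p = 0.0405; adjusted p = 0.208 with an estimated correlation). The count of 249 was 513 without Huh7 knockdown replicate 3 and lay between 7 and 138 without Huh7 knockdown replicate 1, Hep-3B knockdown replicate 3 or any of the 4 control arrays.

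**Figure D4:**
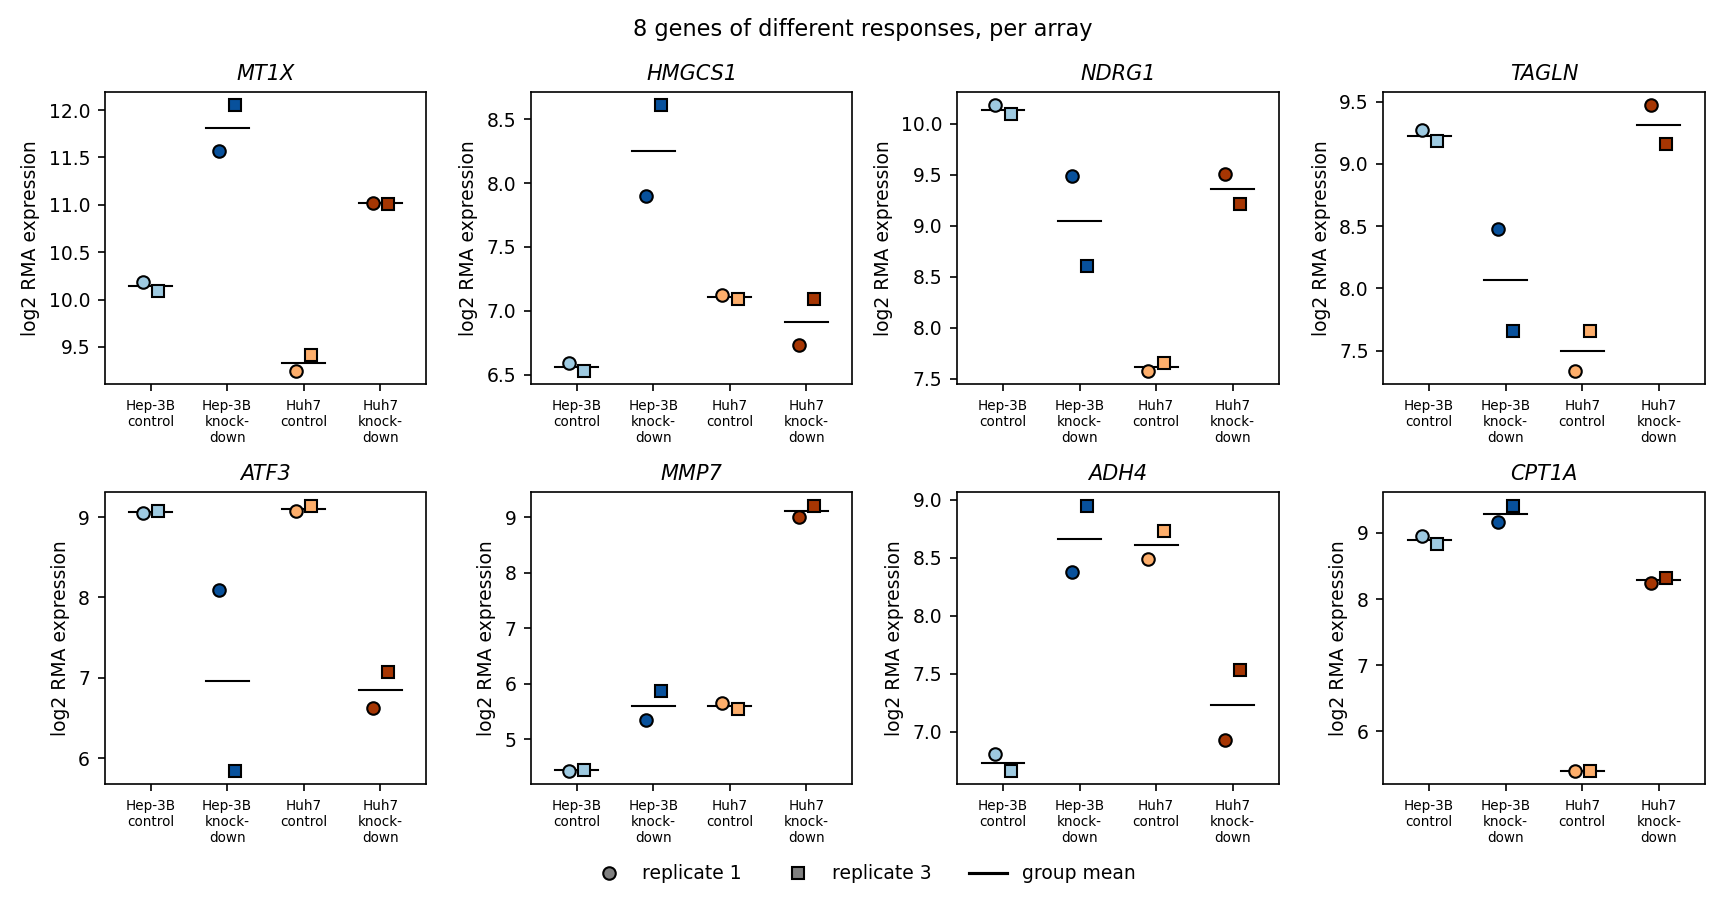
Log2 RMA expression of MT1X, HMGCS1, NDRG1, TAGLN, ATF3, MMP7, ADH4 and CPT1A in each array; circles are replicate 1, squares replicate 3, black lines group means, and each vertical axis has its own range. NDRG1, TAGLN and ADH4 lie on opposite sides of their controls in the 2 lines, and ATF3 was at 8.09 and 5.84 in the Hep-3B knockdown arrays.

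The control arrays give the background against which the knockdown acted. Between the Huh7 and Hep-3B controls 6457 of 19775 genes differed, 3505 higher in Huh7 and 2952 lower. VIM was 4.18 higher in Huh7 (SE 0.16, limma adjusted p = 3.77e-07) and CDH2 lower, at -0.82 (limma adjusted p = 0.00205), while CDH1 differed by -0.24 (limma adjusted p = 0.185). CPT1A and TAGLN, which knockdown raised in Huh7, were lower in Huh7 controls, at -3.49 (limma adjusted p = 9.06e-08) and -1.72 (limma adjusted p = 0.000611).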

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

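The tests of uneven knockdown, of knockdown strength per array and of a varying culture state, the wider interval in the test of mixed cells and the gene list test of the difference between lines were chosen only after the results had been seen.

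The knockdown effect differed between the lines for 249 genes by the test of the difference itself (limma, Huh7 minus Hep-3B). That count was 513 without Huh7 knockdown replicate 3, 138 without Huh7 knockdown replicate 1, 65 without Hep-3B knockdown replicate 3, 12 and 30 without Hep-3B control replicates 1 and 3, and 13 and 7 without those of Huh7. The largest differences were those of TAGLN (2.96), NDRG1 (2.84) and C6 (2.57) upwards and ADH4 (-3.31), CYP17A1 (-2.90) and G0S2 (-2.62) downwards. The Hep-3B controls of G0S2, at 4.80 and 4.99 near the array medians, left little room for a fall. The test of the difference does not by itself separate a response of the line from a difference in knockdown strength. For 8 of the 249 genes, which changed in both lines in opposite directions, the values argue against knockdown strength alone. Weaker silencing would shrink a change rather than reverse it. Of the 27 gene lists 10 differed between lines with the preset correlation and 0 with an estimated correlation. Of 11777 unnamed probe sets, which the gene comparisons left out, 56 are array controls. Among the other 11721, 29 were higher and 49 lower in Hep-3B knockdown than in its controls, and 261 were higher and 225 lower in Huh7 knockdown.

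In Hep-3B 137 genes changed, and in Huh7 2666. At an unadjusted limma p under 0.05 the counts were 3491 and 5441. The SD of the log2 changes over genes was 0.247 and 0.318, with a median SE of 0.113 in both. The gap thus overstates how far the sizes of the responses differed, since it depends on the adjusted threshold. The explanations weighed here are for the gap in adjusted counts, not for the 249 genes whose change differed between the lines. Copy number differences between the Huh7 pools would shift neighbouring genes together. Of the Huh7 calls 0% lay in blocks of 50 neighbouring genes with a median change over 0.3 (largest block median 0.228). This argues against shifts of that size over whole blocks. It cannot speak to shorter stretches or smaller shifts, since the blocks include dim genes, which show changes poorly. Unsilenced cells mixed into Hep-3B knockdown replicate 1 would let its changes be predicted from those of replicate 3. KLHL23 gives a share of 48.8% for cells silenced as in replicate 3, each array being set against the control of its number. Observed over predicted was 1.17 (95% interval over genes 1.04 to 1.32) for 160 genes fallen at least 2-fold in Huh7. For 105 risen ones it was 0.938 (0.859 to 1.01). The fallen genes met the criterion set beforehand against mixing, an interval without 1, but that interval took the share as exact although KLHL23 was read on single arrays; a wider interval that adds this spread, made after the result was seen, was 0.809 to 2.18 for fallen and 0.75 to 1.37 for risen genes, so that mixing cannot be told apart from weaker silencing. Uneven knockdown is a candidate explanation, with 1134 genes without replicate 1 against 16 without replicate 3, 0 without either Hep-3B control, 25 without either Huh7 control and 54 without either Huh7 knockdown array, although leaving out an array that differs from its replicate lowers the estimated spread whatever the reason, and a difference between the lines in their response to KLHL23 loss stays open as untested.

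Stress and immediate early genes differed between knockdown replicates: over 81 members of the immediate early and unfolded protein lists, replicate 3 minus 1 was -0.363 in Hep-3B (95% interval over genes -0.478 to -0.246) and 0.114 in Huh7 (0.026 to 0.207). Strength of the knockdown in each array cannot be told apart from other sources, since KLHL23 differed by -1.06 in Hep-3B and 0.0955 in Huh7 between these arrays, and the interval of the Huh7 value reaches both sides of the bound of 0.2 times the Hep-3B difference. A culture state that varied between cultures cannot be told apart either, since the spread of these genes between the Huh7 knockdown arrays, 1.87 times that of genes matched on level (1.5 to 2.28; 3.17 in Hep-3B), restates the pattern, the control arrays gave 1.2 in Hep-3B and 1.09 in Huh7, and the labels do not say that replicates were separate cultures. The intervals treat genes as independent, which genes of a shared response are not, and so are too narrow. An effect of KLHL23 loss on these genes stays open as untested.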

How the results depend on the processing

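The gene list test of the difference between lines was chosen only after results were seen, and leaving out Hep-3B-shKLHL23 replicate 1 was singled out after them. With 2 arrays per group, leaving out an array leaves a lone sample that is assumed to vary like the other groups. Probe sets near background show changes poorly. Of 201 named gene results under 18 other settings (3585 values), 3009 kept direction and side of the threshold, 502 lost their call, 64 gained a call and 10 reversed; for 54 gene list results under 19 settings (1026 values) these were 928, 64, 13 and 21. Of called results 0 reversed. Of 47 named genes called in Hep-3B 0 kept the call in every setting, since some settings called 0 genes there, and in Huh7 50 of 105 did. The cause was not tested for the changes below, except that fewer arrays, fewer genes or more features tested are part of some settings.

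Genes changed in Hep-3B numbered 236 among 12472 genes above the median level, 850 with an intensity trend and robust eBayes (479 higher), 671 with array weights (352), 623 over all probe sets (269) and 0 with each line fitted alone, where 3731 had an unadjusted limma p under 0.05. Leaving out an array gave 0 to 1134: 1134 without Hep-3B-shKLHL23 replicate 1 (136 of the 137 among them), 16 without its replicate 3, 0 without Hep-3B-shLuc replicate 1 or 3 (2209 and 2075 at an unadjusted limma p under 0.05), 25 without either Huh7-shLuc array and 54 without either Huh7-shKLHL23 array. In Huh7 the count was 1578 fitted alone, 4643 over all probe sets, 1151 with a fold of at least 1.5, and 562 to 3037 without an array (562 and 566 without Huh7-shLuc replicates 3 and 1, 1447 without Huh7-shKLHL23 replicate 1). On average it was 5507 over all probe sets, 588 with the fold and 1165 to 3773 without an array (1445 and 1165 without Hep-3B-shLuc replicates 1 and 3, 1527 without Hep-3B-shKLHL23 replicate 3, 1320 and 1403 without Huh7-shLuc replicates 1 and 3). The difference between lines gave 560 with the trend, 510 over all probe sets and 7 to 513 without an array. The control lines gave 14085 over all probe sets, 3678 with the fold and 4504 to 7049 without an array.

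KLHL23 in Hep-3B stayed at -1.14 and passed with array weights (limma adjusted p = 0.0424; range over alternatives 0.000784 to 0.36). It lay between -1.67 and -0.61 without an array, passing without Hep-3B-shKLHL23 replicate 1. In Huh7 it passed in every setting run. The correlation between lines was 0.493 above the median level and 0.345 to 0.438 without an array, lowest without Hep-3B-shKLHL23 replicate 3. Lists called with an estimated correlation were 0 in Hep-3B, 0 in Huh7, 0 on average and 0 for the difference, and fry called 0, 13, 16 and 4.

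The replicate numbers do not pair the samples by these data: deviations of arrays with the same number correlated at -0.07 in Hep-3B and 0.062 in Huh7. With the number as a block 423 genes changed in Hep-3B (232 higher), with all 137 among them, and KLHL23 in Hep-3B was -1.14 (limma adjusted p = 0.0395; range over alternatives 0.000784 to 0.36). With the block as a random effect 106 genes changed in Hep-3B and KLHL23 did not pass (limma adjusted p = 0.0905).

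Results that turned direction had not been called. With the mean of a gene's probe sets ZEB2 in Hep-3B was 0.034 and PECAM1 in Huh7 -0.22, and list means were -0.0252 for actin and -0.0257 for cholangiocyte markers in Hep-3B and 0.0562 for liver transcription factors and -0.0135 for endothelial markers in Huh7. The direction of the test turned for matrix remodelling in Hep-3B above the median level (mean 0.0258), and fry opposed camera for the mesenchymal list in Hep-3B (-0.0215) and liver transcription factors in Huh7 (0.0170). Without an array in turn, ranges in Hep-3B were COLEC11 -0.19 to 0.66, VIM -0.084 to 0.39, TWIST1 -0.025 to 0.12, SNAI1 -0.15 to 0.010, and list means of -0.0578 to 0.0137 (mesenchymal), 0.0044 to 0.050 (actin), -0.0040 to 0.0380 (cholangiocyte), 0.0043 to 0.0154 (KEAP1-NRF2) and -0.0285 to 0.0320 (stellate cell). In Huh7 they were ZEB2 -0.077 to 0.041, TWIST1 -0.039 to 0.0027, SNAI1 -0.12 to 0.29, and list means of -0.0175 to 0.0515 (liver transcription factors), -0.0067 to 0.0639 (endothelial), -0.0838 to -0.0444 (Kelch-like), -0.0853 to 0.12 (cholesterol) and -0.321 to 0.107 (cell cycle). The cell cycle list passed upwards without Huh7-shKLHL23 replicate 1 (camera adjusted p = 0.00349) with the preset correlation; its estimated correlation was 0.77, with which all arrays gave camera adjusted p = 0.852.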

Other observations

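The tests of cross-hybridization and of glucocorticoid signalling, and the metallothionein group itself, were chosen only after the results had been seen.

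Metallothioneins are small proteins that bind zinc and copper. Of 10 measured genes 8 passed as higher and 0 as lower in each line, 7 of the 8 on probe sets prone to cross-hybridization, by 1.27 to 3.54 in Hep-3B (median of the 10 genes 1.66) and 1.44 to 1.95 in Huh7 (1.67). The 3.54 is that of MT1M, whose Hep-3B control arrays, at 2.66 and 2.58, lay below the arrays' lower quartile. MT3 (0.24 in Hep-3B and 0.32 in Huh7) and MT4 (0.32 and 0.07) did not pass in either line. Among stress-induced genes picked after their values were seen, HMOX1, which degrades haem, rose in Huh7 (0.73, limma adjusted p = 0.0122) and was at 0.43 in Hep-3B (limma adjusted p = 0.154). The chaperone HSPH1 rose in Huh7 (0.69, limma adjusted p = 0.005) and was at 0.40 in Hep-3B (limma adjusted p = 0.0948). DNAJB1 did not pass in Hep-3B (0.55, limma adjusted p = 0.13) or Huh7 (0.47, limma adjusted p = 0.0922).

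For the rise of metallothionein genes in both lines, glucocorticoid signalling, which induces these genes, would raise its other targets. The upper 95% bound of the median over 8 targets was 0.204 in Hep-3B (median -0.071) and 0.113 in Huh7 (median -0.342). In Huh7 TSC22D3 (-1.81) and FKBP5 (-0.39) fell. This argues against glucocorticoid signalling only as far as these 8 targets report it. The interval resamples genes and not arrays, and ZBTB16 and CRISPLD2 were dim, at mean levels of 3.56 and 4.57. The bound of 0.5 that decided the test was set after the values had been seen. It replaced a median below 0 in both lines, which the data also met. Cross-hybridization with a transcript of a single risen member cannot be told apart from a rise of the family, because 1 member, MT1M, passed on a probe set outside the class prone to it, while such probe sets of MT1G, MT3 and MT4 did not pass and had mean levels of 3.09, 4.92 and 4.75, below or near the array medians. Metal exposure cannot be told apart either, since the zinc exporter SLC30A1 was at 0.182 in Huh7 (95% interval -0.0565 to 0.421) and 0.372 in Hep-3B (0.133 to 0.611), which lies below the 0.5 set as a bound against it in Huh7 and reaches above it in Hep-3B. An effect of KLHL23 loss stays open as untested, as does an effect of the hairpin on other transcripts.

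On average over the lines 3089 genes changed, and the highest count among the other splits of the arrays within lines was 249. That split has the real labels with knockdown and control exchanged in 1 line, so its count is that of the difference between lines, and the highest of the remaining splits gave 45. The 18 splits are too few for a share under 0.05 (1 of them, the real one, gave as many genes). Without an array the count of 3089 was 1445 and 1165 for Hep-3B control replicates 1 and 3, 1527 for Hep-3B knockdown replicate 3, and 1320 and 1403 for Huh7 control replicates 1 and 3.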
